A study of Mus musculus with 6 samples.

How the data were processed

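RNA from 6 samples of sorted embryonic day 11.5 mouse cells was amplified to biotin-labelled cRNA and hybridised to Illumina arrays, per the labels' protocols. The values used are the intensities that the authors deposited for each sample, linear probe brightness with the background still in it. How the scanner output was summarised, and whether any scaling was applied, is not given in the sources used here. The deposited intensities were all positive, had medians between 91.3 and 96 per array, and were not equalized between arrays. A second table holds 36 per-array columns whose names match no sample label; none of these values was used, and only its probe annotation was taken. Detection p-values and negative controls belong to those columns, so the planned normalization from them was replaced, as described next, and slide position was not used as a block.

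Background was estimated on each array as the mode of the intensities below 300, with an SD from the values under the mode. The mode lay between 80.0 and 84.3. A probe counted as above background when it exceeded the mode by 1.64 SD, the one-sided 0.05 level. Intensities were corrected with normexp fitted on all probes (offset 16), quantile normalized and taken to log2 in limma 3.58.1 (R 4.3.3, data.table in version 1.17.8). Probes above background on at least 3 of the 6 arrays were kept, 23808 of 45281. All 45281 probe identifiers were found in the annotation. Current symbols came from a RefSeq gene table of assembly GRCm38.p6, used for names only, through the Entrez identifier for 29586 probes and the accession for 2759; the array's own symbol was kept for 12936. No coordinates are printed, since no genome build is named beside the probes. As a check of the identifiers, the differences of 2 probes of the same gene correlated at r = 0.787 across 4871 genes with several probes, against 0.00788 with genes shuffled; genes are not independent replicates. Each gene was represented by its kept probe with the highest mean. In 71 genes, probes were called in opposite directions.

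The comparison was fitted with limma (lmFit and eBayes, 2-sided) on 3 CD45-positive and 3 CD45-negative arrays, as CD45-positive minus CD45-negative, with Benjamini-Hochberg adjustment over 16642 genes and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, for 23 lists with at least 5 measured members. Camera with an estimated correlation and the fry rotation test were alternatives. Counts of list members were adjusted over all genes and over the list alone. The groups, the tests, the 24 gene lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took the sort markers, the 12 higher and 12 lower genes with the largest differences whose groups did not overlap (leaving out clone-type and predicted names), all measured retinoid genes, and in each other list up to 4 called members with the largest differences and up to 2 called against the majority.

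Where no probe of a gene was above background on any array of a group, the difference is a bound, written as "at least N-fold". It sets the mean of the brighter group against the mean of, per array, the higher of the lowest value among probes above background and the gene's own value. Offset and background compress differences of dim genes. The number of arrays limits the precision. The labels do not say whether the samples of a group came from separate sorts, so p-values measure the spread between these samples, which may be technical.

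The chain was tested on simulated data made from the real probes, in 10 data sets with genes changed by known amounts. Every probe had the same noise, the median SD of the real genes, and a baseline from the CD45-negative arrays. The rates therefore do not describe genes with a wider spread, such as S100a9 (SD 1.13 over the CD45-positive arrays). Of 50 genes changed by each of 0.5, 1, 2 and 4 on the log2 scale, on average 47, 45, 44 and 43 passed the background filter and were tested. Of those tested, 35.4%, 83.1%, 97.0% and 99.3% were recovered (about 15234 genes tested in all), and the median estimates were 0.41, 0.84, 1.55 and 3.54. Changed genes lost to the filter are not in these rates. Unchanged genes made up 8.17% of the calls, above the nominal 5%. In the first data set, a moved list of 30 genes was called, and 0 of 99 random lists. The noise was drawn for each probe on its own, so simulated genes were not correlated. Real lists had estimated correlations up to 0.669. The simulation therefore could not show false list calls that arise from correlated genes. With as many genes changed as in the real fit, the unchanged genes had a median estimate of 0.05, and 3.99% of them were called. Of the genes changed at least 2-fold that passed the filter, 99.1% were recovered (15430 genes tested).

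The alternatives were no background correction, median scaling, the deposited values on a log2 scale, no filter, a stricter filter, the mean of all probes, every probe on its own, array weights, an intensity trend with robust variance, the replicate number as a block, both other list tests, each array left out in turn, and an offset of 50. The offset of 50 was added after seeing the data. With an array left out, the tested genes and their probes are those of all 6 arrays; this was decided after a first run had picked them anew each time, which lost the call of the retinoid list in 3 of the runs instead of 1. Process terms of the probe annotation were tested after the data were seen. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).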

Results

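Gene expression was measured with Illumina bead arrays in cells sorted from the aorta-gonad-mesonephros region of E11.5 mouse embryos. This region is where the first haematopoietic stem cells appear, and the title of the study places retinoic acid signalling in that process. The labels give 3 arrays of cells carrying the AA4.1/VEC label together with CD45, and 3 arrays of cells carrying the AA4.1/VEC label without CD45. AA4.1 is the antigen encoded by Cd93, VEC is read here as VE-cadherin, encoded by Cdh5, and CD45 is the pan-leukocyte phosphatase encoded by Ptprc. Whether every sorted cell carried both AA4.1 and VEC is not given in the sources used here. Each array held 45281 probes, and between 48.7% and 51.4% of them lay above background. The median intensity per array was between 91.3 and 96. Arrays of the same population correlated at r between 0.988 and 0.992 across probes (6 pairs), and arrays of different populations at r between 0.912 and 0.919 (9 pairs); probes are not independent replicates.

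The CD45-positive cells carried blood transcripts at high level, and the CD45-negative cells carried endothelial and matrix transcripts. Among 16642 genes tested, 4846 were higher and 4009 lower in the CD45-positive cells (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 and 3). Differences of at least 2-fold were found for 1385 higher and 1810 lower genes, and differences of at least 8-fold for 215 higher and 348 lower genes. For 412 of the higher genes the tested probe was not above background on any CD45-negative array, and for 684 of the lower genes it was not above background on any CD45-positive array. The median SD of a gene was 0.14 over the CD45-positive arrays and 0.12 over the CD45-negative arrays on the log2 scale. In 10012 genes (60.2%) the values of the groups did not overlap, where chance gives 10%. The 2-fold counts depend on how background is treated: 964 genes were higher at least 2-fold without background correction.

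The antigens of the sort were checked first. Ptprc was higher in the CD45-positive cells by 1.98 ± 0.20 (log2 difference ± SE, adjusted p = 1.8e-05, limma with Benjamini-Hochberg), with mean levels of 6.96 in the CD45-positive and 4.99 in the CD45-negative cells. None of its probes was above background on any CD45-negative array, which makes the difference at least 2.82-fold. Its other probes gave 1.07 and 0.38, and the probe with 0.38 was not above background on any array. Cdh5 had a log2 difference of -5.32 ± 0.16 (adjusted p = 3.0e-09), with a mean level of 6.83 in the CD45-positive and 12.15 in the CD45-negative cells. A second Cdh5 probe gave -4.85. Cd93 differed far less, with a log2 difference of -0.74 ± 0.20 (adjusted p = 0.0102) and mean levels of 11.43 and 12.17. The plot of identity genes shows these values on each array.

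**Figure D1:**
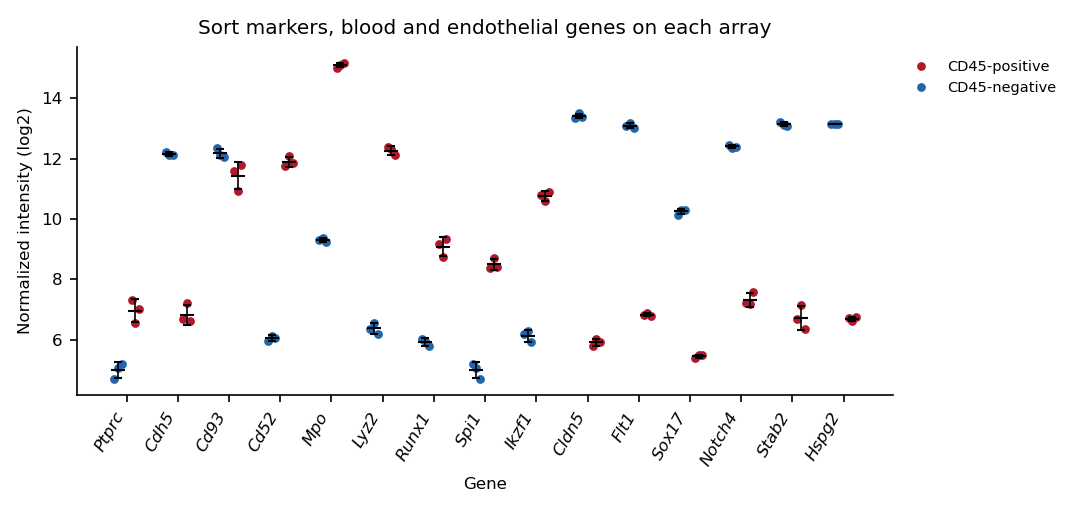
Normalized log2 intensity (vertical axis) of 15 genes (horizontal axis) on the 3 CD45-positive arrays in red and the 3 CD45-negative arrays in blue; each point is an array, and the black bars give the mean and SD of each group. The points of Cdh5 center on 6.83 in the CD45-positive and on 12.15 in the CD45-negative cells, while those of Cd93 lie at 11.43 and 12.17.

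The 12 genes with the largest differences in each direction are given here one by one, and were not tested as groups. Higher in the CD45-positive cells were Tcrb-V8.2 (log2 difference 6.66), the chemokine Ccl4 (6.60), Igh-6, an immunoglobulin heavy chain transcript (6.54), Cytip (6.48) and Cox6a2 (6.40). Next came lysozyme Lyz2 (5.89), the leukocyte antigen Cd52 (5.85), the granule protein Mpo (5.80), S100a8 (5.74) and the granule protein Prtn3 (5.68). Ccl3 (5.58) and Lyz1 (5.55) completed the 12 highest. Mpo reached a mean level of 15.10, against 9.30 in the CD45-negative cells. Lower in the CD45-positive cells were the tight junction protein Cldn5 (log2 difference -7.51), the imprinted gene Mest (-7.03), endothelin Edn1 (-7.01), Oit3 (-7.00), Ccn2 (-7.00), Gpr182 (-6.99), Mmrn2 (-6.93), Cavin2 (-6.52), perlecan Hspg2 (-6.46), the scavenger receptor Stab2 (-6.42) and Igfbp5 (-6.40). The endothelial protocadherin Pcdh12 was not above background on any CD45-positive array and was at least 89.6-fold lower there. The adjusted p of these 24 genes was at most 2.1e-06 (limma, Benjamini-Hochberg), S100a8 having both the highest adjusted p and the widest error, at ± 0.42.

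Endothelial genes were lower in the CD45-positive cells across vessel types. Of 31 measured members of the pan-endothelial list, 29 were lower and none was higher (30 lower when adjusted over the list alone), with a mean log2 difference of -3.85. The examples with the largest differences beside Cldn5 and Mmrn2 were the VEGF receptor Flt1 (-6.27) and the transcription factor Sox11 (-6.10), which is in the fixed list but is not a usual endothelial marker. Of 20 arterial genes 18 were lower, among them the gap junction protein Gja5 (-5.02), Notch4 (-5.09) and Sox17, which was at least 26.9-fold lower. Sox17 is also in the pan-endothelial list. The chemokine receptor Cxcr4 (4.34) and the Notch ligand Jag2 (0.64), both also expressed outside arteries, were higher. Of 11 venous and lymphatic genes 10 were lower, among them the ephrin receptor Ephb4 (-5.30), the hyaluronan receptor Lyve1 (-5.17) and the apelin receptor Aplnr (at least 19.2-fold). Stab1, at 1.32, was higher on its brightest probe, but its mean over probes had a difference of -0.73. Camera gave adjusted p = 1.2e-21 for the pan-endothelial, 9.1e-09 for the arterial and 3.0e-07 for the venous and lymphatic list (limma, Benjamini-Hochberg over 23 lists). All 3 calls held with an estimated correlation, with adjusted p = 0.0194, 0.0194 and 0.0248.

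The CD45-positive cells carried transcripts of several blood lineages. Of 35 pan-leukocyte genes 34 were higher, with a mean log2 difference of 3.33, among them Nckap1l (5.50) and the adaptor Tyrobp (5.34); the actin regulator Cotl1 was lower (-0.47). Of 25 macrophage genes 22 were higher, including the complement genes C1qb (4.93) and C1qc (4.86), while the mannose receptor Mrc1 was lower (-2.05). Of 17 granulocyte and mast cell genes 15 were higher and none lower, Mpo, S100a8 and Prtn3 among them. Of 15 lymphoid genes 11 were higher, among them the B-cell receptor component Cd79b (3.47), Vpreb3 (3.25), the interleukin 7 receptor Il7r (3.25) and Ltb (3.21), and Gimap6 was lower (-0.58). Of 23 cytokine receptor genes 16 were higher, including Cx3cr1 (4.05) and Csf1r (3.79), and 5 were lower, including the erythropoietin receptor Epor (-1.19). Il7r is in this list too, and so is Cxcr4 of the arterial list. The camera adjusted p (limma, Benjamini-Hochberg) was 5.8e-19 for the pan-leukocyte list, and 0.0166 with an estimated correlation. It was 4.4e-10 for macrophage, 5.2e-08 for granulocyte and mast cell, 0.000367 for lymphoid and 0.000367 for cytokine receptor genes. With an estimated correlation those calls were lost, with adjusted p = 0.137, 0.112, 0.0565 and 0.112.

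Transcription factors of blood stem cells were mostly higher in the CD45-positive cells, while surface markers of stem and progenitor cells split. Of 29 transcription factors 19 were higher and 5 lower (20 and 5 adjusted over the list alone), with a mean log2 difference of 1.13. Ikzf1 (4.62), the myeloid and lymphoid regulator Spi1 (at least 8.14-fold), Gfi1 (3.40) and Runx1 (3.15), which is required for blood formation from endothelium, were higher. Hoxa5 was lower (-1.47). The camera adjusted p was 0.000361, and adjusted p = 0.191 with an estimated correlation. Of 17 surface markers 7 were higher and 7 lower. Cd27 (4.95) and Cd44 (4.31) were higher, while Robo4 (-4.09), Esam (-3.72) and the integrin Itga2b (-3.07) were lower. Robo4 and Esam are also in the pan-endothelial list, and Itga2b is also in the megakaryocyte and platelet list. Their differences are thus not separate from those of these lists. For that list the mean was 0.23, the median -0.07 and the camera direction downward, with adjusted p = 0.975, so no shift was called.

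**Figure D2:**
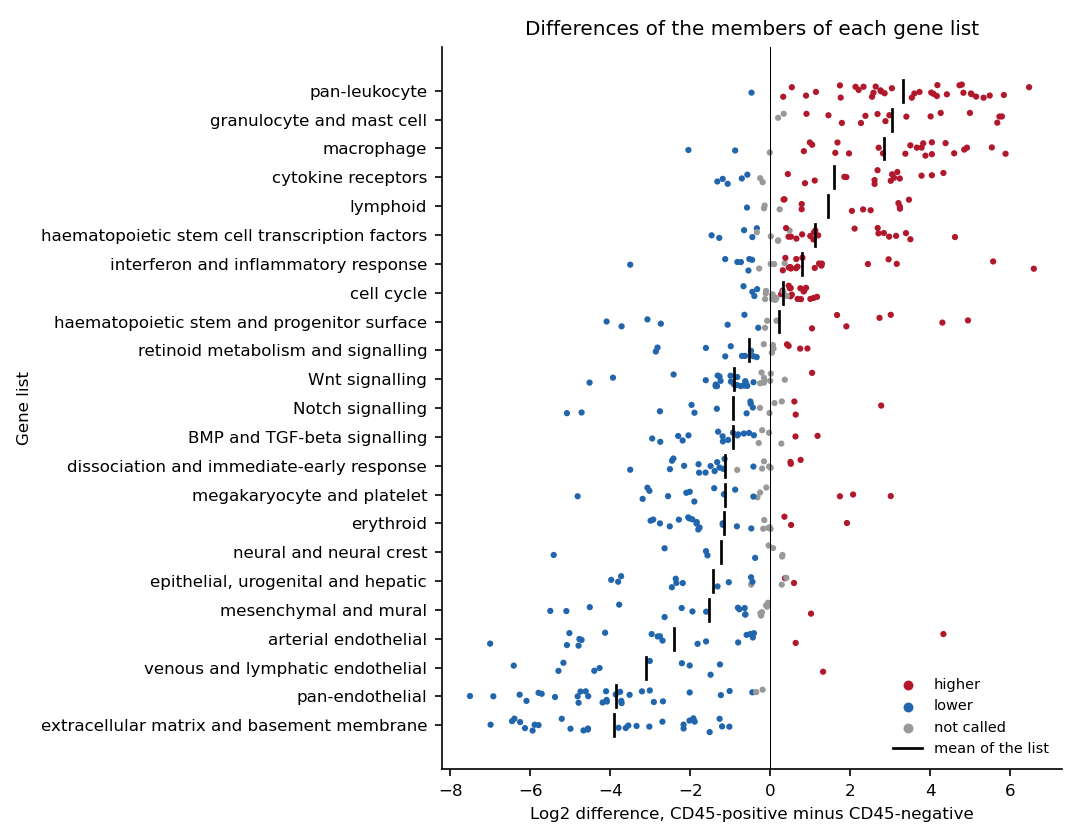
Log2 difference between CD45-positive and CD45-negative cells (horizontal axis) for each measured member of 23 gene lists (vertical axis); points are genes, red if higher, blue if lower and gray if not called, and the black bar is the mean of the list. The means run from -3.90 for extracellular matrix genes to 3.33 for pan-leukocyte genes.

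The comparison bears on where the retinoic acid machinery named in the title is expressed. Of 18 measured retinoid genes 10 were lower in the CD45-positive cells and 4 higher, with the same counts adjusted over the list alone, and the mean log2 difference was -0.52. The largest differences were those of the receptor Rarb (-2.86 ± 0.10), itself a known target of retinoic acid, the lipid carrier Fabp5 (-2.82 ± 0.13), the transglutaminase Tgm2 (-1.61 ± 0.21) and the receptor Rarg (-1.12 ± 0.12). The degrading enzyme Cyp26a1 was not above background on any CD45-positive array and was at least 1.42-fold lower. Cyp26b1, also not above background there, was at least 1.08-fold lower, and its call was lost without CD45-positive replicate 1 (adjusted p = 0.0738) or 3 (0.0653) or CD45-negative replicate 2 (0.0539). The receptor Rxrb (0.75 ± 0.11) and the enzyme Rdh11 (0.46 ± 0.12) were higher. The synthesizing enzyme Aldh1a2 had mean levels of 5.90 in the CD45-positive and 5.86 in the CD45-negative cells, near background in both, with a log2 difference of 0.04 ± 0.17. Calls of 3 more genes with small differences depended on single arrays, as with Crabp2 without CD45-positive replicate 1 (-0.30) or CD45-negative replicate 1 (-0.40). The others were Rdh5 without CD45-positive replicate 1 (-0.30) or 3 (-0.31) or CD45-negative replicate 1 (-0.26) or 3 (-0.32), and Ncor1 without CD45-positive replicate 1 (0.37) or 3 (0.32) or CD45-negative replicate 2 (0.40) or 3 (0.33). Rara (0.07), Rxra (-0.16) and Rdh10 (0.08) were also not called, and Aldh1a1, Aldh1a3 and Stra6 were not above background on at least 3 arrays. The camera adjusted p of the list was 0.0315 (limma, Benjamini-Hochberg), and adjusted p = 0.137 with an estimated correlation. The call was also lost without CD45-negative replicate 1 (-0.49, adjusted p = 0.0530), with the deposited values as they are (-0.41, adjusted p = 0.0596) and with a stricter background limit on all arrays (-0.40, adjusted p = 0.261).

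**Figure D3:**
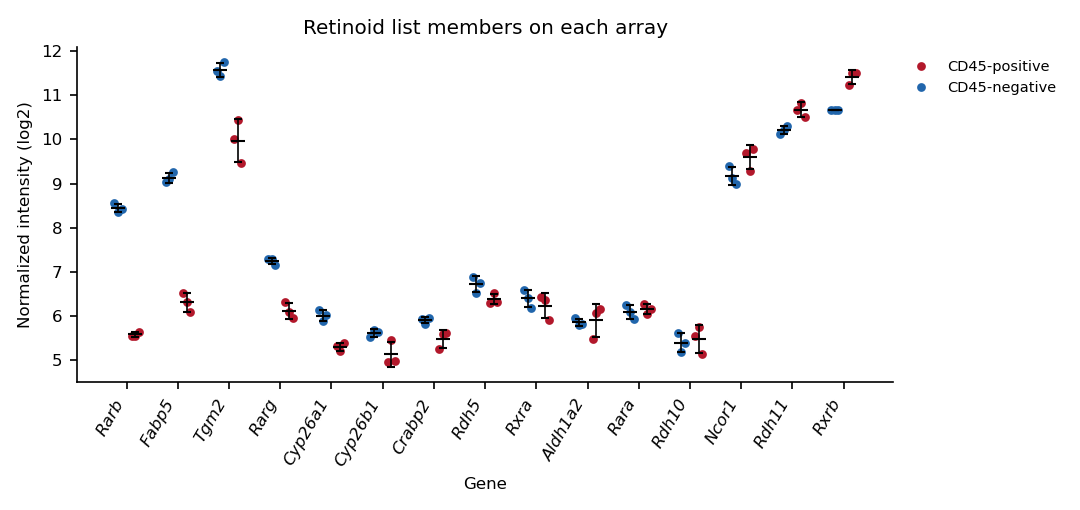
Normalized log2 intensity (vertical axis) of 15 of the 18 measured retinoid genes, those named in the text (horizontal axis, ordered by their difference) on the 3 CD45-positive arrays in red and the 3 CD45-negative arrays in blue, with the mean and SD of each group in black. Rarb and Fabp5 lie well apart between the groups, whereas the points of Aldh1a2 overlap at means of 5.90 and 5.86.

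Genes of other developmental pathways were mostly lower in the CD45-positive cells. Of 34 Wnt genes 25 were lower and 1 higher (25 and 2 adjusted over the list alone), with a mean log2 difference of -0.91. The repressor Tcf7l1 (-4.52), the secreted antagonist Sfrp1 (at least 11.4-fold) and the ligand Wnt2 (at least 4.62-fold) were lower, and the pathway inhibitor Axin1 was higher (1.05). Of 17 Notch genes 10 were lower and 3 higher (10 and 4 adjusted over the list alone). The target gene Hey1 (-4.72) and the ligand Dll4 (at least 4.94-fold) were lower, and Dtx4 was higher (2.78). Members such as Notch4 and Jag2 are also in the arterial list, so the Notch result is not separate from that list. Of 21 BMP and TGF-beta genes 15 were lower and 2 higher. The ligand Bmp4 (-2.95) and the inhibitory Smad6 (-2.19) were lower, and the repressor Skil was higher (1.19). By camera the adjusted p was 3.4e-07 for Wnt, 0.0120 for Notch and 0.000104 for BMP and TGF-beta genes (limma, Benjamini-Hochberg). With an estimated correlation the calls were lost, with adjusted p = 0.0526, 0.112 and 0.0913.

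Matrix transcripts, and most of the measured transcripts of other cell types that the sort could hold, were lower in the CD45-positive cells. The matrix list names no cell type and does not tell endothelial from other sources. All 28 measured extracellular matrix and basement membrane genes were lower, with a mean log2 difference of -3.90, a camera adjusted p of 1.1e-20 and adjusted p = 0.0166 with an estimated correlation (limma, Benjamini-Hochberg); Igfbp7 differed by -6.26. Of 20 mesenchymal and mural genes 13 were lower, including Dcn (at least 37.7-fold), Acta2 (-5.10) and Col1a1 (at least 15.5-fold), and Dlk1 was higher (1.02). Of 24 erythroid genes 16 were lower, including the globin Hba-a1 (-2.76) and the anion exchanger Slc4a1 (-2.51), while the transferrin receptor Tfrc was higher (1.92). Of 18 megakaryocyte and platelet genes 12 were lower (13 adjusted over the list alone), including Vwf (-4.82), and 3 were higher. Endothelium also expresses Vwf, which is in the pan-endothelial list as well. Of 16 epithelial, urogenital and hepatic genes 11 were lower (12 adjusted over the list alone) and 2 higher. The lower genes included the plasma proteins Apoa2 (-3.98 ± 0.47), Apoa1 (-3.80 ± 0.52) and Ttr (-3.73 ± 0.49), whose SD over the CD45-negative arrays was 1.20, 1.33 and 1.22. Of 9 neural genes 5 were lower, including Gap43 (at least 37.3-fold). The camera adjusted p was 8.7e-06 for mesenchymal, 9.3e-05 for erythroid, 0.000387 for megakaryocyte, 0.00364 for epithelial and 0.0236 for neural genes. With an estimated correlation none of these 5 was called, with adjusted p = 0.162, 0.191, 0.0772, 0.424 and 0.124.

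Cell cycle genes were slightly higher in the CD45-positive cells, and genes of the immediate-early response lower. Of 32 cell cycle genes 16 were higher and 4 lower, with a mean log2 difference of 0.33. The helicase subunits Mcm6 (1.17) and Mcm7 (1.09) and the licensing factor Cdc6 (1.01) were higher, and the mitotic kinases Plk1 (-0.67) and Cdk1 (-0.45) were lower. Of 29 interferon and inflammatory genes 18 were higher, including Tlr2 (3.17), and 7 were lower, including the cytokine feedback inhibitor Socs3 (-3.50). Of 23 genes induced by tissue dissociation or as immediate-early genes 15 were lower in the CD45-positive cells, including Dusp1 (-2.51), Hspa1a (-2.46) and Ier3 (-2.42), and Egr2 was higher (0.76). Socs3 belongs to this list too. For these lists camera gave adjusted p = 0.0227 for the cell cycle, 0.0213 for the interferon and inflammatory and 0.000130 for the dissociation list (limma, Benjamini-Hochberg). With an estimated correlation none was called, with adjusted p = 0.455, 0.112 and 0.191. In all, 8 lists were higher and 14 lower, of which 1 and 4 were called with an estimated correlation. The fry rotation test called 8 lists higher and 14 lower. That test asks whether the genes of a list shift at all, not whether they shift more than other genes. Of all tested genes 53.2% were called. In the lists for which no separate count is given, adjustment over the list alone gave the same counts.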

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

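Chosen after the data were seen were the normexp offset of 50 and keeping the tested genes and probes of all arrays when an array is left out. Ptprc, Cdh5 and Cd93 and the pan-endothelial and pan-leukocyte lists kept their direction and stayed past the threshold under every alternative that gave a value for them; the stricter background limit leaves Ptprc untested. The slide block was not run, because slide positions could not be tied to samples. The count of genes higher at least 2-fold was 890 with the deposited values as they are and 921 with the stricter background limit on all arrays, which also gave 1077 genes lower at least 2-fold and 5 lists higher and 10 lower; that limit tests fewer genes (11620) and removes those dim in one group. With an estimated correlation camera called 1 list higher and 4 lower, and the fry rotation test called 8 higher and 14 lower. The retinoid list was no longer called with the deposited values (-0.41, adjusted p = 0.0596), the stricter limit (-0.40, adjusted p = 0.261) and the estimated correlation (-0.52, adjusted p = 0.137). The Wnt list lost its call with the estimated correlation (-0.91, adjusted p = 0.0526). The estimated correlations of the retinoid (0.0096), Notch (0.0085), interferon (-0.0019), lymphoid (-0.037) and neural (-0.099) lists lay below the preset 0.01. These values argue against a larger correlation as the cause of the calls lost by these lists in that test. Apart from this and the changed number of genes, the cause was not tested. The stricter limit also lost the calls of the mesenchymal (-0.20, adjusted p = 0.171), epithelial (0.303), lymphoid (0.265), interferon (0.257) and cell cycle (0.0635) lists and left the neural list untested. The reversed gene values were those of Aldh1a2 (-0.068 with array weights), Rdh10 (-0.0033 with array weights) and Stab1 (-0.73 with the mean of its probes, which differ in direction), besides those with an array left out. Leaving out each array in turn gave 4197 to 4835 genes higher and 3617 to 3979 lower, 1369 to 1407 and 1762 to 1857 at least 2-fold, and 8 lists higher and 13 to 14 lower. Ptprc ranged from 1.80 to 2.18, Cdh5 from -5.51 to -5.21 and Cd93 from -0.91 to -0.49, and the mean of the retinoid list from -0.55 to -0.49, of the Wnt list from -0.95 to -0.87, of the pan-endothelial list from -3.88 to -3.83 and of the pan-leukocyte list from 3.31 to 3.34. The retinoid list lost its call without CD45-negative replicate 1 (-0.49, adjusted p = 0.0530). Values that were near 0 changed sign: Aldh1a2 without CD45-positive replicate 2 (-0.039) and 3 (-0.088), against 0.253 without CD45-positive replicate 1, Rara without CD45-negative replicate 3 (-0.0106), against 0.145 without CD45-negative replicate 1, Rxra without CD45-positive replicate 3 (0.0043), against -0.263 without CD45-negative replicate 3, and Rdh10 without CD45-positive replicate 2 (-0.0494) and CD45-negative replicate 2 (-0.022), against 0.255 without CD45-positive replicate 3. Of 2135 values of named genes under the alternatives, 2083 kept direction and side of the threshold, 43 lost their call and 9 reversed; 14 genes account for the changes. With the replicate number as a block 4635 genes were higher and 3888 lower. Same-numbered samples had residual correlations of 0.198, -0.124 and -0.143, and not every sample correlated best with its own number. These values give no sign that the numbers pair samples. They cannot exclude pairing, because the pairs are few and the residuals within a group are tied to each other. Genes near background carry the least information.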

Other observations

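Chosen after the result was seen were the process terms, the use of Ptprc and of the deposited values to test explanations, admixture tested within the list, both tests of array-wide scaling and the counts over other splits. Genes named here were chosen after their values were seen unless named above. Among 434 process terms of the probe annotation, 28 were higher and 61 lower in the CD45-positive cells (limma's camera, Benjamini-Hochberg), and 0 were called with an estimated correlation. Of 76 genes of nucleosome assembly, 58 were higher and 3 lower (adjusted p = 1.9e-07, and 0.377 with an estimated correlation), led by the histone variant Macroh2a1 (2.58) and the histone genes H2bc8 (2.19) and H2ac18 (2.12). All 13 genes of antigen presentation through MHC class II were higher (adjusted p = 3.7e-07, and 0.377 with an estimated correlation), including H2-DMa (3.23), Cd74 (3.13) and Ifi30 (2.55). Of 48 genes of ribosomal RNA processing 28 were higher and 3 lower (adjusted p = 0.00255, and 0.377 with an estimated correlation). Of 45 axon guidance genes 26 were lower and 2 higher (adjusted p = 3.7e-05, and 0.377 with an estimated correlation), including Efnb1 (-4.28), the VEGF co-receptor Nrp1 (-4.13), Sema6a (-4.04) and Robo1 (-3.81).

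Among single homeobox genes, Hoxa7 (2.98) and Hoxa9 (2.71) were higher in the CD45-positive cells, whereas Hoxa5 (-1.47), Hoxb5 (-3.54), Hoxb2 (-2.66) and Hoxb4 (-1.76) were lower. Hoxb7, also lower, was not above background on any CD45-positive array. Homeobox genes were not tested as a group.

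Cdh5 and 29 of 31 pan-endothelial genes were far lower in the CD45-positive arrays although both populations carry the VEC label. Exchanged group labels are excluded by Ptprc, higher by 1.98 in the arrays labelled CD45-positive, and quantile normalization as the whole cause by the deposited values without it, with a mean log2 difference of -3.47 for the list. Admixture of CD45-negative cells as the only source of the endothelial signal left was first tested between lists, without a decision: the median share left was 3.36% over 24 bright endothelial and 1.66% over 19 bright matrix genes, a ratio of 2.03 against a factor of 2 fixed in advance (95% interval 1.04 to 5.39 over resampled genes). Within the endothelial list the shares, which cells of the mean CD45-negative profile would make equal, ran from 0.115% (Esm1) to 46.4% (Egfl7). The lowest shares are imprecise. That of Esm1 is less signal than the background SD, and Sox17 (0.80%) was not above background on any CD45-positive array. The upper over the lower quartile was 8.10 (5.43 to 10.03 with the error of the measurement, background SD included, against an upper 95% limit of 1.68 for equal shares). This excludes admixed cells with the mean profile of the CD45-negative arrays only as the sole source of the signal left. Some such admixture, beside expression of list members by the CD45-positive cells themselves, is not excluded. The spread was chosen after resampling the genes had given 2.71 to 19.3 against a limit of 3. Admixture of a subset with another profile stays open. A gate that took AA4.1-positive cells lacking VEC, or loss of the endothelial programme in cells that gain CD45, was not tested.

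Some late neutrophil transcripts were lowest on the array of CD45-positive replicate 2, where S100a8 was at 11.34 against 12.68 and 12.97 on replicates 1 and 3, and Ltf at 8.89 against 10.68 and 11.51. Array-wide scaling or RNA yield is excluded as the whole cause: in the deposited values S100a8, S100a9 and Ltf had a median deviation from the mean of replicates 1 and 3 of -1.80 there, and random sets matched on expression one of 0.0929 (-0.35 to 0.46). A smaller share of late-stage neutrophils in that sample is a hypothesis: 8 further late neutrophil genes had a median deviation of -0.31, with 7 under that mean but only 5 lowest on that array (Hp, Cxcr2 and Mmp25 were lowest on replicate 1), below the central 95% of 10000 random sets matched on expression (-0.18 to 0.22), but short of the -0.5 set in advance, so it stays undecided. Macrophage genes went the other way, with a median deviation of 0.40, and 24 of 25 lay above the mean of replicates 1 and 3 on that array. Regulation within the same cells was not tested.

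Hepatic transcripts on the CD45-negative arrays were highest in replicate 3 and lowest in replicate 2, where Apoa1 was at 10.78 and 8.20. Array-wide scaling is excluded as the whole cause: in the deposited values 8 hepatic genes of the fixed list differed between those replicates by a median of 2.61, and random sets matched on expression by one of 0.0944 (-0.18 to 0.37). Liver cells in differing shares are a candidate explanation: 14 further hepatocyte genes had a median difference of 1.57, in the same direction in 12, including Ambp (3.48) and Serpina6 (3.31). The fibrinogen genes Fga (7.82, 6.30 and 8.41 in replicates 1 to 3 on the first of 2 probes, which share the order) and Fgg (7.51, 6.28 and 8.19) kept the same order, whereas Serpina3h (12.57, 12.40 and 12.55) was nearly flat. Against it, the sort for AA4.1/VEC should remove hepatocytes, and the probe of Alb, an abundant hepatocyte transcript, was not above background on any array (82.2 against a limit of 95.1 in replicate 3), though a single probe may have failed; Fgb was not above background either, and the design names no biological difference among these replicates to test.

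The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 8855 genes, 3195 of them at least 2-fold, and 22 lists, and 1 of the 10 splits, the real one, reached each of these. The highest of the other splits called 0 genes (limma; up to 312 at an unadjusted p under 0.05), 0 at least 2-fold, and 16 lists; camera with the preset correlation thus calls many lists in splits that mix the populations unevenly.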
